A study of Mus musculus with 8 samples.

How the data were processed

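Expression was measured in 8 mouse libraries made with the TruSeq RNA kit, version 2, which does not mark strand, from RNA with an integrity number above 8, per the labels' protocols. Per the submitters' processing notes the genome build was mm10 and the tools were TopHat2 2.0.10, Bowtie2 2.1.0.0, HTSeq and DESeq 1.14.0. Roles of these tools, the annotation and the strand setting of the counting are not given in the sources used here. The deposited values have the unit signal: gene counts that the authors divided by 1 size factor per library, as the values themselves show. In each library all values above 0 (100% within a tolerance of 0.01 reads) were whole multiples of the value of 1 read, which was fitted starting from the smallest value above 0. Whole reads were recovered by dividing by it. This assumes that the smallest value stands for 1 read.

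Samples were grouped by the labels' titles into repopulating microglia, wild-type microglia and bone-marrow macrophages. Columns of the deposited table were matched to samples by name and replicate number. The columns named for repopulating cells and for controls were matched first, the controls having replicates 1 and 2 alone as the wild-type samples do, and the remaining 3 columns were taken as the bone-marrow macrophages. No column was left unused. Replicates differed by more than counting noise and were all kept. Total reads per library ran from 5918944 to 12476427. The table held 23413 gene symbols, 7003 of them at 0 in every library, and no entry without a gene name. Where 1 group had no read of a gene, folds were bounded with 3 reads over the group, and where it had 1 to 3 reads the ratio of reads has a 95% interval. Reads carried no molecular identifiers, so such intervals and floors cover counting error only.

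Tests used log2(normalised count + 1) of the 11415 genes with at least 10 normalised counts in at least 2 libraries. These genes held 99.9% of the reads. One model over all 8 libraries, without covariates, was fitted with limma 3.58.1 in R 4.3.3, with a variance trend on mean level. The threshold was a Benjamini-Hochberg adjusted p of 0.05 within each comparison, two-sided. Gene lists, 27 in number and fixed before the data were examined together with the groups, the tests and most alternatives, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested. Each list was also tested with an estimated correlation and with fry. With an estimated correlation no list passed in any comparison, while at an unadjusted p under 0.05 there were 4 lists for repopulating against wild-type microglia, 2 for bone-marrow macrophages against wild-type microglia and 2 for repopulating microglia against bone-marrow macrophages. Count tests on the recovered reads used edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, which left 12 adjusted p-values as NA in each comparison.

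Genes named were, in each comparison, the 10 highest and 10 lowest by log2 fold among those past the threshold with groups that do not overlap and a mean of at least 100 normalised counts in the higher group, leaving out predicted models, clones, small RNA genes and receptor segments. To these came 22 genes fixed in advance and up to 4 members of each list by smallest adjusted p, or the 2 with the highest mean where none passed. The text gives a part of them, and 1 of the genes fixed in advance is not reported here. Coordinates are 1-based, from the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, and span the whole gene. All 225 named genes had 1 locus there. Because strand is not marked, reads of a gene and of an overlapping or antisense partner cannot be told apart, and reads of near-identical copies, such as Ly6c1 and Ly6c2, Schlafen, interferon-induced and histocompatibility genes, are uncertain.

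Checks on simulated data drew counts from the real means with 200 genes changed by known folds, 100 at each size. Of the 4-fold changes 91%, 93% and 99% were recovered for repopulating against wild-type microglia, bone-marrow macrophages against wild-type microglia, and repopulating microglia against bone-marrow macrophages, and of the 2-fold changes 46%, 29% and 48%. False calls made up 6.8%, 6.9% and 4.5% of calls, in fits of 11393, 11348 and 11338 genes. Each gene was drawn with the same spread in every group, and only genes above a minimum mean level were changed. These rates therefore do not cover groups of unequal spread, as the real ones are, or genes with low counts. Alternatives were 3 other pseudocounts, 2 other filters, 3 other scalings, fits without each library, with only the groups compared, with the replicate number as a block, with library weights, with robust variances or without a variance trend, and the count tests. A covariate of Y-linked transcripts and the removal of trends with transcript length and GC content were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.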

Results

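Gene expression was measured by RNA sequencing in 8 mouse libraries from 3 kinds of mononuclear phagocyte: bone-marrow macrophages (n = 3), wild-type microglia (n = 2) and repopulating microglia (n = 3). The bone-marrow macrophage columns of the values were named mono and were assigned by exclusion. Titles of these samples read bm_micro, and their source name reads bone-marrow macrophages. Microglia are the resident macrophages of the brain. The series title names interleukin-1 signalling in the renewal and upkeep of microglia as its subject. Interleukin-1 is an inflammatory cytokine that signals through the receptor Il1r1. Per the labels' protocols, mice received 2 mg tamoxifen under the skin on postnatal days 12 and 14, and diphtheria toxin was injected to deplete microglia. Brain cells were then released with papain, enriched on a Percoll gradient and sorted by flow cytometry. The same protocol text stands on all 8 samples, wild type included, and the labels do not say whether the bone-marrow macrophages were taken from marrow or from brain. Wild-type samples carry the strain label DTR and the other 6 samples DTRmg, so strain label and group could not be separated in the comparisons with wild type. The labels also do not say whether replicates were separate animals, so the p-values measure only the spread between these samples, which may be technical in part.

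Reads counted in genes came to 12476427, 6853696 and 8182515 in bone-marrow macrophage replicates 1 to 3. They came to 7635322 and 7600939 in the wild-type microglia and to 9523997, 5918944 and 6944167 in repopulating microglia replicates 1 to 3. The values analysed were the authors' gene counts divided by a size factor per library, called normalised counts here, and 11415 genes were tested. Fold changes are on the log2(normalised count + 1) scale, which understates the change of genes with low counts.

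The first principal component held 62% of the variance and separated the bone-marrow macrophages, at -77.8 to -74.1, from the wild-type microglia at 61.2 and 65.4. Repopulating microglia lay between them at 32.0, 18.8 and 51.5 for replicates 1 to 3. Replicate 3 of the repopulating microglia stood apart on the second component, at -63.2 against -17.3 and -14.1 for replicates 1 and 2. Across the tested genes, which are not independent replicates, log2 levels of repopulating replicates 1 and 2 correlated at r = 0.979, and those of replicate 3 with them at 0.938 and 0.918. Ribosomal protein genes took 6.04% of the reads of replicate 3, against 9.15% and 9.26% in replicates 1 and 2, 4.90% and 4.26% in the wild-type microglia and 8.83%, 8.45% and 8.76% in bone-marrow macrophages 1 to 3. Xist is transcribed from the inactive X chromosome of female cells. It stood at 0.57, 567 and 538 normalised counts in bone-marrow macrophages 1 to 3, at 532 and 604 in wild-type microglia and at 706, 0 and 596 in repopulating microglia 1 to 3. Summed counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were 799, 1.06 and 0 in bone-marrow macrophages, 0 in both wild-type libraries and 1.89, 1086 and 274 in repopulating microglia. These values argue against all replicates of bone-marrow macrophages, or of repopulating microglia, coming from the same animals. Both wild-type libraries were alike in them, so whether these came from separate animals stays open.

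**Figure D1:**
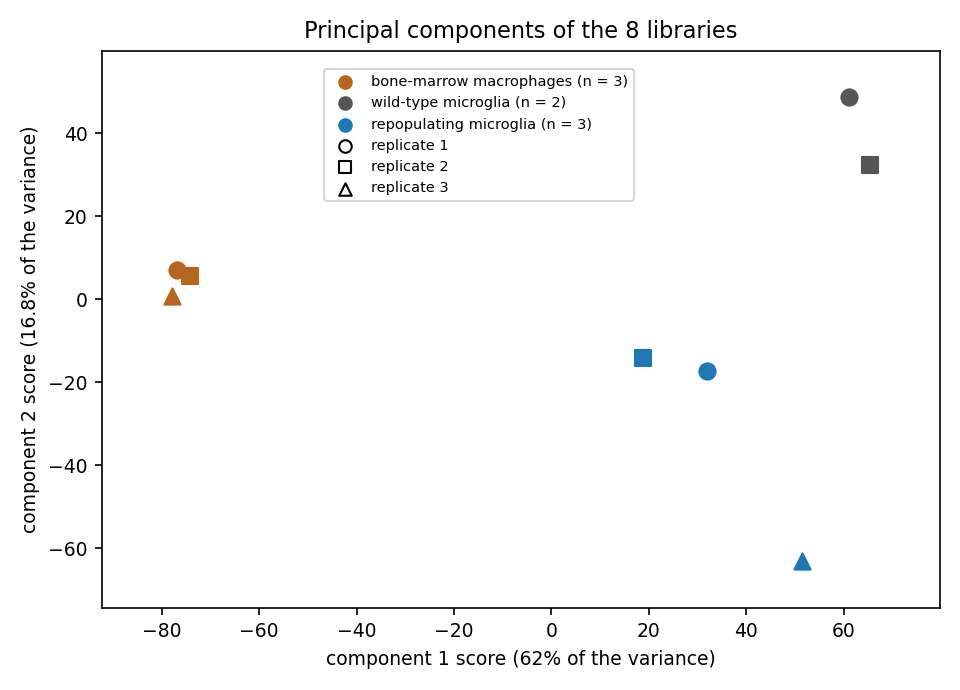
First 2 principal components of log2(normalised count + 1) over the tested genes, in arbitrary units, with 1 point per library and its replicate number. Bone-marrow macrophages lie at -77.8 to -74.1 on the first component and wild-type microglia at 61.2 and 65.4, with repopulating replicate 3 at -63.2 on the second component.

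The first comparison set repopulating microglia against wild-type microglia. Cx3cr1, the fractalkine receptor of microglia (GRCm38 chromosome 9, 119901616 to 120069879, minus strand), fell by 1.61 ± 0.17 on the log2 scale (SE), from 66246 ± 3329 normalised counts (SD, n = 2) to 21834 ± 2385 (SD, n = 3). Bone-marrow macrophages, which share the strain label DTRmg with repopulating microglia, stood near that level at 20093 ± 1775. The fall of Cx3cr1 therefore cannot be told apart from an effect of strain. Ly6c2, a surface antigen of inflammatory monocytes (chromosome 15, 75108158 to 75111970, minus strand), fell by 5.98 ± 0.32, from 1111 ± 359.5 to 16.8 ± 6.11. Ngp, a neutrophil granule protein (chromosome 9, 110419747 to 110423012, plus strand), fell by 3.47 ± 0.21, from 4827 ± 81.1 to 439 ± 77. In the other direction, St8sia1, which makes the ganglioside GD3 (chromosome 6, 142821545 to 142964452, minus strand), rose by 3.60 ± 0.32 from 31.9 ± 6.28 to 410.2 ± 137. Chst2, a carbohydrate sulfotransferase (chromosome 9, 95399292 to 95406722, minus strand), rose by 2.83 ± 0.22, from 39.1 ± 2.11 to 285 ± 22.6. These 5 genes had limma p-values, adjusted by Benjamini-Hochberg as all adjusted p-values here, of 0.00179, 0.000284, 0.000307, 0.000971 and 0.000721 in that order. Ly6c2 shares sequence with Ly6c1, and how the authors' counting split such reads is not given in the sources used here. Ly6c2 and Ngp mark other blood cells. Their falls cannot be told apart from a larger share of such cells in the wild-type libraries.

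In this comparison limma called 983 of 11415 genes, 555 higher and 428 lower in repopulating microglia, and 584 of them changed at least 2-fold. The spread behind these calls was estimated over all 3 groups. Leaving out a bone-marrow macrophage library therefore changed this spread but not the folds. Log2 differences between bone-marrow macrophage replicates had an SD of 0.399 to 0.427, against 0.519 to 1.007 between repopulating replicates. A spread pooled with this tighter group can be too small for repopulating microglia, so the limma p-values of this comparison may be too small. With only the libraries of the 2 groups compared, 68 of the 94 named calls of this comparison were lost. Count tests on the whole reads recovered from the values called 969 genes with edgeR and 1625 with DESeq2, and 917 genes were called by all 3 tools. With libraries scaled to equal totals, which moved the median log2 fold of all genes from -0.02 to -0.13, the 1167 calls split into 441 higher and 726 lower. The count was 67 and 147 without wild-type replicates 1 and 2, and 496, 520 and 528 without bone-marrow macrophages 1, 2 and 3. It was 468 without repopulating replicate 1 and 2958 without repopulating replicate 3. The count of genes changed at least 2-fold was 67, 143, 364 and 1188 without wild-type replicates 1 and 2 and repopulating replicates 1 and 3.

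Interleukin-1 genes did not pass the list test as a group. Il1a, encoding interleukin-1 alpha (chromosome 2, 129299610 to 129309972, minus strand), stood at 1832 ± 479.8 normalised counts (SD, n = 3) in repopulating and 864 ± 24.4 (SD, n = 2) in wild-type microglia. The log2 difference of 1.05 ± 0.28 (SE) did not pass the threshold (limma adjusted p = 0.0503). It passed without bone-marrow macrophage replicate 1 (adjusted p = 0.0395) and without repopulating replicate 3 (0.00235). Over all settings tried its adjusted p lay between 0.00235 and 0.249. Il1r1, the signalling receptor (chromosome 1, 40225080 to 40317257, plus strand), stood at 32.7 ± 5.39 against 13.7 ± 6.37 (log2 1.26 ± 0.43, limma adjusted p = 0.105). Il1b (569 ± 364 against 393 ± 58.8) and the receptor antagonist Il1rn (93.0 ± 42.6 against 251.8 ± 100.2) also did not pass, with limma adjusted p = 0.679 and 0.0682. Without repopulating replicate 3, Il1r1 and Il1rn passed, at log2 1.37 and -1.03 with adjusted p = 0.0435 and 0.00853. Their ranges over all settings were 0.0435 to 0.426 and 0.00853 to 0.405. Of 33 tested genes of the interleukin-1 family and receptor signalling, Irak1, a receptor-associated kinase, rose by 0.77 ± 0.19 and Il1r2, the decoy receptor, fell by 2.83 ± 0.64 (limma adjusted p = 0.041 and 0.0319). Both calls ended without wild-type replicate 1 (adjusted p = 0.29 and 0.224) or 2 (0.116 and 0.159). Both also ended without bone-marrow macrophage replicate 2 (0.0651 and 0.0605) or 3 (0.0705 and 0.0623), or repopulating replicate 2 (0.0751 and 0.054). Irak1 ended without repopulating replicate 1 (0.0775) and Il1r2 without bone-marrow macrophage replicate 1 (0.0661). Over all settings the adjusted p ran from 0.00777 to 0.29 for Irak1 and from 0.00923 to 0.224 for Il1r2. Without repopulating replicate 3, 5 members of the list were called higher and 5 lower, and without bone-marrow macrophage replicate 1, 2 were called higher. Adjusted over the list alone, 2 were higher and 1 lower. The list's median log2 fold was 0.09, its mean -0.07 and its camera adjusted p = 0.66, in a range of 0.419 to 0.989 over the camera settings, which set a list against the other genes. Fry, which tests the members against no change, gave an adjusted p of 0.741 for movement in 1 direction on balance and 0.000291 for change in either, and at an unadjusted limma p under 0.05, 7 members were higher and 5 lower.

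**Figure D2:**
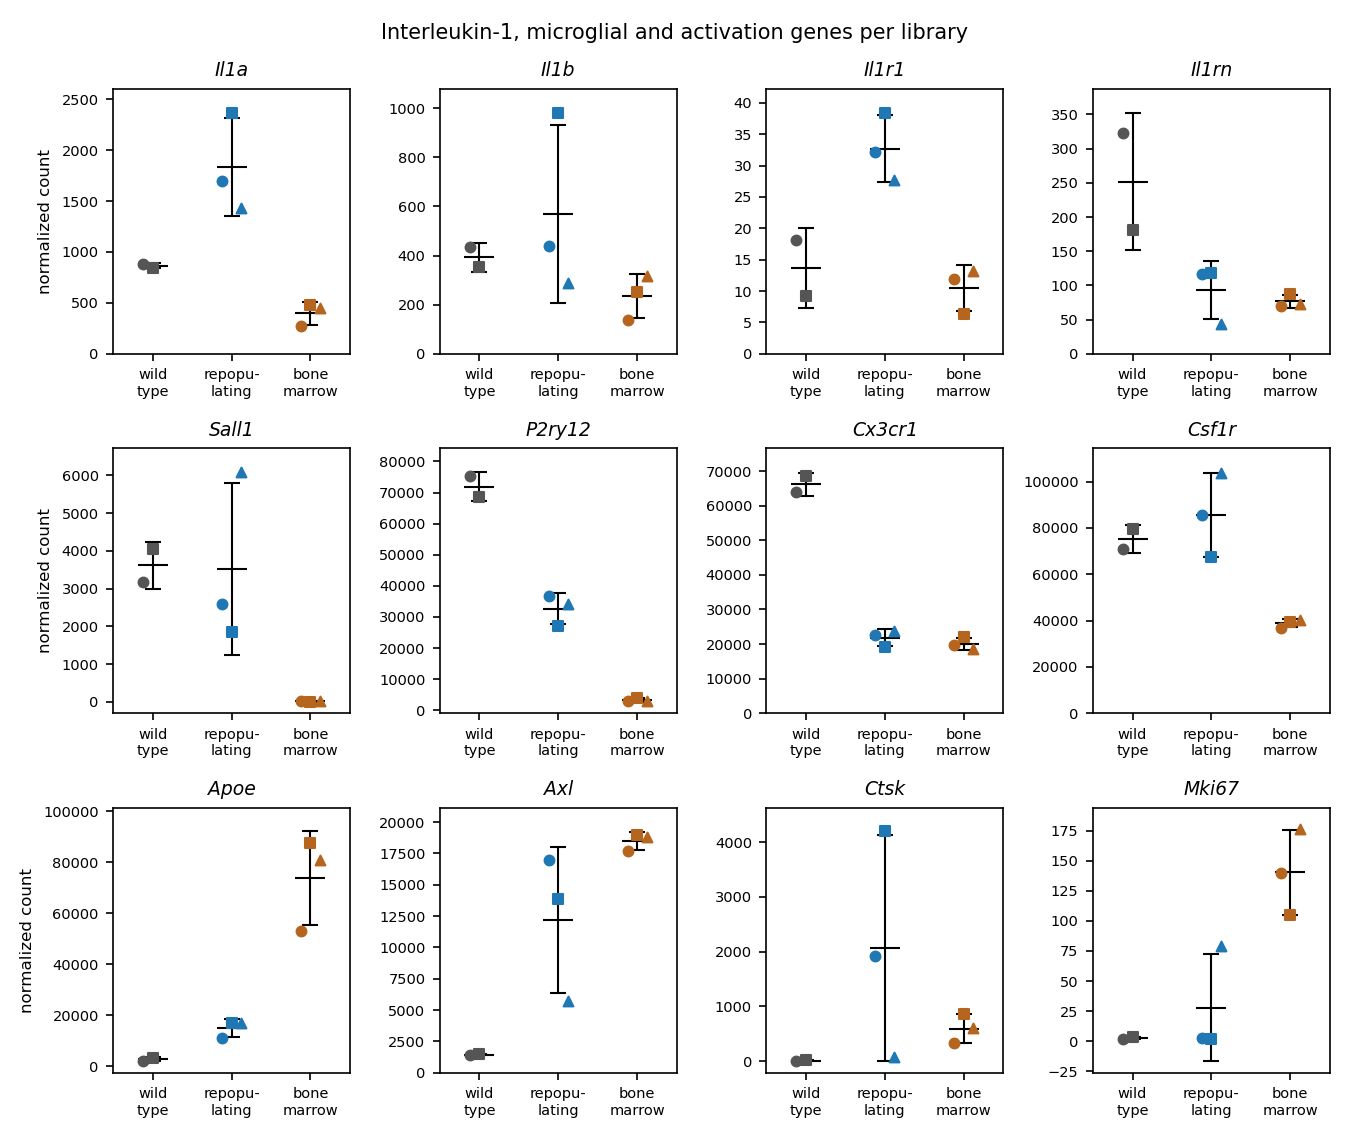
Normalised counts of 12 genes in each library on linear axes, with 1 panel per gene, 1 point per library and a black dash with error bar for the group mean ± SD. Cx3cr1 stood at a mean of 66246 in wild-type microglia, 21834 in repopulating microglia and 20093 in bone-marrow macrophages. Sall1 stood at 20.1 in bone-marrow macrophages.

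Genes of the microglia signature fell in part. Of 41 tested, 10 fell, or 14 adjusted over the list alone, and the median log2 fold was -0.38 (camera adjusted p = 0.000188, and adjusted p = 0.587 with an estimated correlation). The microglia signature's camera adjusted p ranged from 9.31e-08 to 0.587 over the camera settings, and by fry the adjusted p was 0.0833 for 1 direction and 0.000132 for either. P2ry12, the ADP receptor that guides microglial processes (chromosome 3, 59216272 to 59262871, minus strand), fell by 1.15 ± 0.20 (SE), from 71931 ± 4595 (SD, n = 2) to 32645 ± 5015 (SD, n = 3). Its limma adjusted p was 0.0137, or 0.14 and 0.0828 without wild-type replicates 1 and 2, in a range of 3.12e-06 to 0.14 over all settings. Sall1, a transcription factor of microglial identity, stood at 3520 ± 2265 against 3618 ± 619, and Csf1r, the receptor microglia need to survive, at 85607 ± 18265 against 75336 ± 5985. Neither passed (limma adjusted p = 0.838 and 0.66), nor did Tmem119 or Siglech, other surface markers of microglia, at log2 -0.49 and 0.13. The Sall1 mean hides a wide spread, with 2594, 1864 and 6101 normalised counts in repopulating replicates 1 to 3. The wild-type libraries held 3180 and 4056. Signature genes called lower numbered 1 and 2 without wild-type replicates 1 and 2. Leaving out repopulating replicate 3 gave 20 called lower and 1 higher, and Tmem119 passed at log2 -0.62.

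Of 27 disease-associated microglia genes, 13 rose, or 19 with 1 lower adjusted over the list alone, and the median was 0.97 (camera adjusted p = 2.9e-10, and adjusted p = 0.296 with an estimated correlation). Apoe, a lipid carrier (chromosome 7, 19696109 to 19699188, minus strand), rose by 2.42 ± 0.30 (SE), from 2812 ± 846 (SD, n = 2) to 15001 ± 3513 (SD, n = 3). Axl, a receptor kinase for apoptotic cells (chromosome 7, 25757273 to 25788705, minus strand), rose by 2.93 ± 0.39, from 1448 ± 45.0 to 12167 ± 5822 (limma adjusted p = 0.00373 for Apoe and 0.00477 for Axl). Without wild-type replicate 1 these became 2.11 and 2.90 with adjusted p = 0.068 and 0.0724, the highest over all settings, whose lowest were 1.29e-12 and 7.5e-14. Members called higher numbered 8 without each bone-marrow macrophage replicate 1, 2 or 3, 2 without wild-type replicate 1 or 2, and 7 without repopulating replicate 1. Without repopulating replicate 3, 21 were called higher and 1 lower, and 1 was called lower without repopulating replicate 2. Ctsk, a bone-matrix protease outside that list, had the highest fold of the comparison by the rule for named genes. It stood at 1928, 4203 and 70.3 normalised counts in repopulating replicates 1 to 3 and at 0 and 19.3 in the wild-type libraries. Its call (limma adjusted p = 0.0305) held without repopulating replicate 3 (2.83e-05) and ended without repopulating replicate 1 (0.0868) or 2 (0.0554). It also ended without wild-type replicate 1 (0.255) or 2 (0.0641) and bone-marrow macrophage replicate 1 (0.0569), 2 (0.0613) or 3 (0.0634). Over all settings its adjusted p ran from 2.83e-05 to 0.255.

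Of 42 genes of the type I interferon response, 12 rose and Slfn1 fell, or 18 rose and 1 fell adjusted over the list alone, with a median of 0.78 (camera adjusted p = 1.83e-09, and adjusted p = 0.513 with an estimated correlation). The adjusted p of the type I interferon response lay between 2.1e-16 and 0.513 over the camera settings, and by fry it was 0.0687 for 1 direction and 0.000625 for either. Slfn5, of the Schlafen family, whose members resemble each other, rose by 2.28 ± 0.19 (SE) from 184.5 ± 23.7 (SD, n = 2) to 909 ± 197 (SD, n = 3). Eif2ak2, the kinase that senses double-stranded RNA, rose by 1.82 ± 0.20 (limma adjusted p = 0.000971 for Slfn5 and 0.00225 for Eif2ak2). Interferon genes called higher numbered 5 without each bone-marrow macrophage replicate 1, 2 or 3, 2 without wild-type replicate 1 or 2, 6 without repopulating replicate 1 and 31 without repopulating replicate 3. Slfn1 was not called without wild-type replicate 1 or 2. Of 21 genes in the list CSF1 receptor and haematopoietic growth-factor receptors, 7 rose, or 9 with 3 lower adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.0277, and adjusted p = 0.308 with an estimated correlation). Csf2ra, the GM-CSF receptor alpha chain, rose by 1.56 ± 0.16 from 325 ± 4.76 to 961.5 ± 56.3 (limma adjusted p = 0.00162). That list's camera call ended without repopulating replicate 1 (adjusted p = 0.0773) and with quantile normalisation (0.173), in a range of 0.00673 to 0.308 over the camera settings. Of its genes, 3 were called higher without each bone-marrow macrophage replicate 1, 2 or 3, 1 without wild-type replicate 1 or 2, and 2 without repopulating replicate 1. Leaving out repopulating replicate 3 gave 11 higher and 4 lower. Lysosome and phagocytosis genes rose in 7 of 33 cases and Cd300a fell, with 14 higher and 3 lower adjusted over the list alone and a median of 0.28 (camera adjusted p = 0.000396, and adjusted p = 0.503 with an estimated correlation). Cd300lf, a lipid-binding surface receptor, rose by 1.75 ± 0.23 from 45.0 ± 10.4 to 153.5 ± 30.0 (limma adjusted p = 0.00452). Lysosome genes called higher numbered 4, 3 and 4 without bone-marrow macrophages 1, 2 and 3, 1 without wild-type replicate 1 or 2, 3 without repopulating replicate 1 and 18 without repopulating replicate 3. Cd300a was not called without wild-type replicate 1 or 2.

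Cell isolation can induce the immediate-early and dissociation-response genes. Of 30 tested, Ier2, Ier3, Dusp2 and Egr3 rose and Dusp6 fell, or 7 higher and 2 lower adjusted over the list alone, with a median of 0.39 (camera adjusted p = 0.0127, and adjusted p = 0.6 with an estimated correlation). The camera call of this list ended without wild-type replicate 1 (adjusted p = 0.311) or repopulating replicate 1 (0.0561) and with quantile normalisation (0.103), in a range of 0.000433 to 0.6 over the camera settings. By fry the adjusted p was 0.258 for 1 direction and 0.00284 for either. Genes called higher numbered 2 and 1 without bone-marrow macrophages 2 and 3, 2 without repopulating replicate 2 and 10 without repopulating replicate 3. Neither Ier2, Ier3, Dusp2 nor Egr3 was called without wild-type replicate 1, wild-type replicate 2 or repopulating replicate 1. Dusp6 was not called without wild-type replicate 1 or 2, and 2 genes were called lower without repopulating replicate 3.

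Marker lists of neutrophils, recruited monocytes and macrophages, dendritic cells, and T and NK cells were lower in repopulating microglia by camera. Neutrophil and granule markers fell in 15 of 16 cases, also adjusted over the list alone, with a median of -3.56 (camera adjusted p = 2.07e-17, and adjusted p = 0.185 with an estimated correlation). Camp, an antimicrobial peptide precursor, fell by 3.17 ± 0.23 (SE) from 1681 ± 169.5 (SD, n = 2) to 188 ± 32.0 (SD, n = 3). Lcn2, which binds bacterial iron chelators, fell by 3.33 ± 0.24 (limma adjusted p = 0.000557 for Camp and for Lcn2). Genes of recruited monocytes and macrophages fell in 18 of 40 cases, 22 adjusted over the list alone, with a median of -1.76 (camera adjusted p = 5.43e-12, and adjusted p = 0.487 with an estimated correlation). S100a11, a calcium-binding protein of that list, fell by 2.85 ± 0.19 (limma adjusted p = 0.000549). Both lists had 8 members called lower without wild-type replicate 1, and 9 recruited monocyte and macrophage genes were called higher without repopulating replicate 3. Dendritic cell markers fell in 6 of 13 cases, 7 adjusted over the list alone, with a median of -1.72 (camera adjusted p = 7.16e-05, and adjusted p = 0.147 with an estimated correlation). The lectin Cd209a fell by 2.92 ± 0.26, from 190 ± 5.14 to 24.2 ± 1.07 (limma adjusted p = 0.000971). Without wild-type replicate 1 or 2, 2 dendritic markers were called lower. Of 13 T and NK cell markers, Gzma, Nkg7, Gzmb and Cd3d fell, with 6 lower and 1 higher adjusted over the list alone and a median of -1.83 (camera adjusted p = 0.00253, and adjusted p = 0.503 with an estimated correlation). The adjusted p of the T and NK cell markers lay between 4.37e-06 and 0.503 over the camera settings, and by fry it was 0.0592 for 1 direction and 0.00284 for either. These 4 genes were not called without wild-type replicate 1, which held 302 normalised counts of the granzyme gene Gzma against 44.7 in replicate 2. Nkg7 and Gzmb were also not called without repopulating replicate 1, and Cd3d was not called without wild-type replicate 2 or any 1 bone-marrow macrophage replicate.

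Cell cycle and proliferation genes, which include the proliferation marker Mki67, gave no call of 45 with limma, also adjusted over the list alone. At an unadjusted p under the 0.05 threshold 2 were higher and 4 lower, edgeR called 0, DESeq2 called 1 lower, and the median was -0.11 (camera adjusted p = 0.641). Mki67 stood at 2.83, 1.48 and 79.5 normalised counts in repopulating replicates 1 to 3 and at 2.14 and 3.05 in the wild-type libraries (limma adjusted p = 0.514). Without wild-type replicate 2 the list cell cycle and proliferation passed as lower (median -0.32, camera adjusted p = 0.0158), in a range of 0.0158 to 0.964 over the camera settings. Of its genes, 4 were called higher and 2 lower without repopulating replicate 3.

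Among 33 cytokines and chemokines, Tnf, Ccl3, Igf1, Tnfsf13b and Osm rose and Ccl6, Ccl9 and Ccl22 fell, with 7 higher and 3 lower adjusted over the list alone. The list did not pass (camera adjusted p = 0.401), but passed without repopulating replicate 3 (0.0209), in a range of 0.0209 to 0.908 over the camera settings. The higher and lower counts of cytokines and chemokines were 3 and 1 without bone-marrow macrophage replicate 2 or 3, and 16 and 6 without repopulating replicate 3. The higher counts were 2 and 3 without repopulating replicates 1 and 2. The 8 genes were not called without wild-type replicate 1, and 1 gene, lower, was called without wild-type replicate 2. Of 17 border-associated macrophage markers, Igfbp4, Siglec1 and Stab1 rose and Mgl2 fell, with 5 higher and 2 lower adjusted over the list alone. Their camera adjusted p was 0.0775, or 0.00836 and 0.00318 without wild-type replicate 2 and repopulating replicate 3, in a range of 0.00318 to 0.678 over the camera settings. Igfbp4, which binds insulin-like growth factors, rose by 1.78 ± 0.15 (SE; limma adjusted p = 0.000971) and was called without any 1 library. Siglec1, Stab1 and Mgl2 were not called without wild-type replicate 1, and Stab1 and Mgl2 not without wild-type replicate 2. The border-associated counts were 10 and 2 without repopulating replicate 3, and without repopulating replicate 2 the lower count was 2. Of 27 antigen presentation genes, the class II chains H2-Ab1 and H2-Eb1 and their chaperone Cd74 fell and H2-D1 rose, with 4 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.801). These 4 genes were not called without wild-type replicate 1 or 2. H2-D1 was also not called without bone-marrow macrophage replicate 2 or repopulating replicate 1, nor H2-Eb1 without any 1 bone-marrow macrophage replicate or repopulating replicate 1, nor H2-Ab1 without bone-marrow macrophage replicate 3. The higher count was 3 without repopulating replicate 2, and without repopulating replicate 3, 6 antigen presentation genes were called higher and 6 lower.

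Other lists had few calls and no camera call. In complement, C2, Itgax and Itgb2 rose and C5ar2 fell of 18, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0813). The complement list's adjusted p ran from 0.0247 to 0.544 over the camera settings, and by fry it was 0.0407 for 1 direction and 0.000132 for either. Among 22 Toll-like and Fc receptors, Clec4d, Clec4a1, Tlr5 and Clec4a3 fell, or 5 adjusted over the list alone (camera adjusted p = 0.457). In TGF-beta signalling, Tgif1 and Ltbp3 rose and Lrrc33 fell of 21, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.382). Among 38 macrophage transcription factors, Egr2 and Nfkb2 rose and Cebpd fell, also adjusted over the list alone (camera adjusted p = 0.723). Npc2 alone rose of 31 genes of cholesterol synthesis and lipid handling, and it did not pass adjusted over the list alone (camera adjusted p = 0.727). Of astrocyte markers, Aldh1l1 rose of 11, also adjusted over the list alone (camera adjusted p = 0.652). That list passed as lower without repopulating replicate 3 (0.0237), in a range of 0.0237 to 0.989 over the camera settings. Cspg4 rose of 6 oligodendrocyte markers, also adjusted over the list alone, and the list had a median of -0.07, a mean of 0.29 and a test in the higher direction (camera adjusted p = 0.543). Ly6a fell of 14 endothelial and mural markers, or 2 adjusted over the list alone (camera adjusted p = 0.0813). The list passed without wild-type replicate 1 (0.0132) and repopulating replicate 3 (0.00183), in a range of 0.00105 to 0.678 over the camera settings. Bank1 fell of 6 B cell markers, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.279).

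Of the genes named for these 9 lists, Cspg4 was the only one called without wild-type replicate 1 or without wild-type replicate 2. C2, Itgb2, Tlr5, Ltbp3, Lrrc33, Nfkb2, Cebpd, Npc2, Aldh1l1 and Ly6a were also not called without each of bone-marrow macrophage replicates 1, 2 and 3, and C5ar2 not without replicates 1 and 2. C2, C5ar2, Itgb2, Clec4d, Tlr5, Ltbp3, Lrrc33, Cebpd, Npc2 and Aldh1l1 were not called without repopulating replicate 1, nor were C2, C5ar2, Tlr5, Lrrc33, Nfkb2, Npc2 and Ly6a without repopulating replicate 2. Without repopulating replicate 3 the higher and lower counts were 5 and 2 for complement, 5 and 4 for TGF-beta signalling, 5 and 9 for macrophage transcription factors and 5 and 1 for cholesterol synthesis and lipid handling. There 5 Toll-like and Fc receptors were called higher, and 3 astrocyte, 6 endothelial and mural and 3 B cell markers lower, and without repopulating replicate 2, 2 B cell markers were lower.

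Of 5 sex-linked transcripts limma and edgeR called 0, also adjusted over the list alone and at an unadjusted limma p under 0.05 (camera adjusted p = 0.232). DESeq2 called the Y-linked genes Ddx3y, Eif2s3y and Kdm5d as higher. Of 4 tested neuron markers limma and DESeq2 called 0 and edgeR 1 as lower, with 1 lower adjusted over the list alone and at an unadjusted p under 0.05. Epor, the erythropoietin receptor, fell of 2 erythroid markers, also adjusted over the list alone, and was called neither without a wild-type nor without a bone-marrow macrophage replicate, nor without repopulating replicate 1 or 2. Neuron and erythroid markers were too few for the list test. Members named beside a count of 5 or fewer that the rule for named genes leaves out were chosen after their values were seen.

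**Figure D3:**
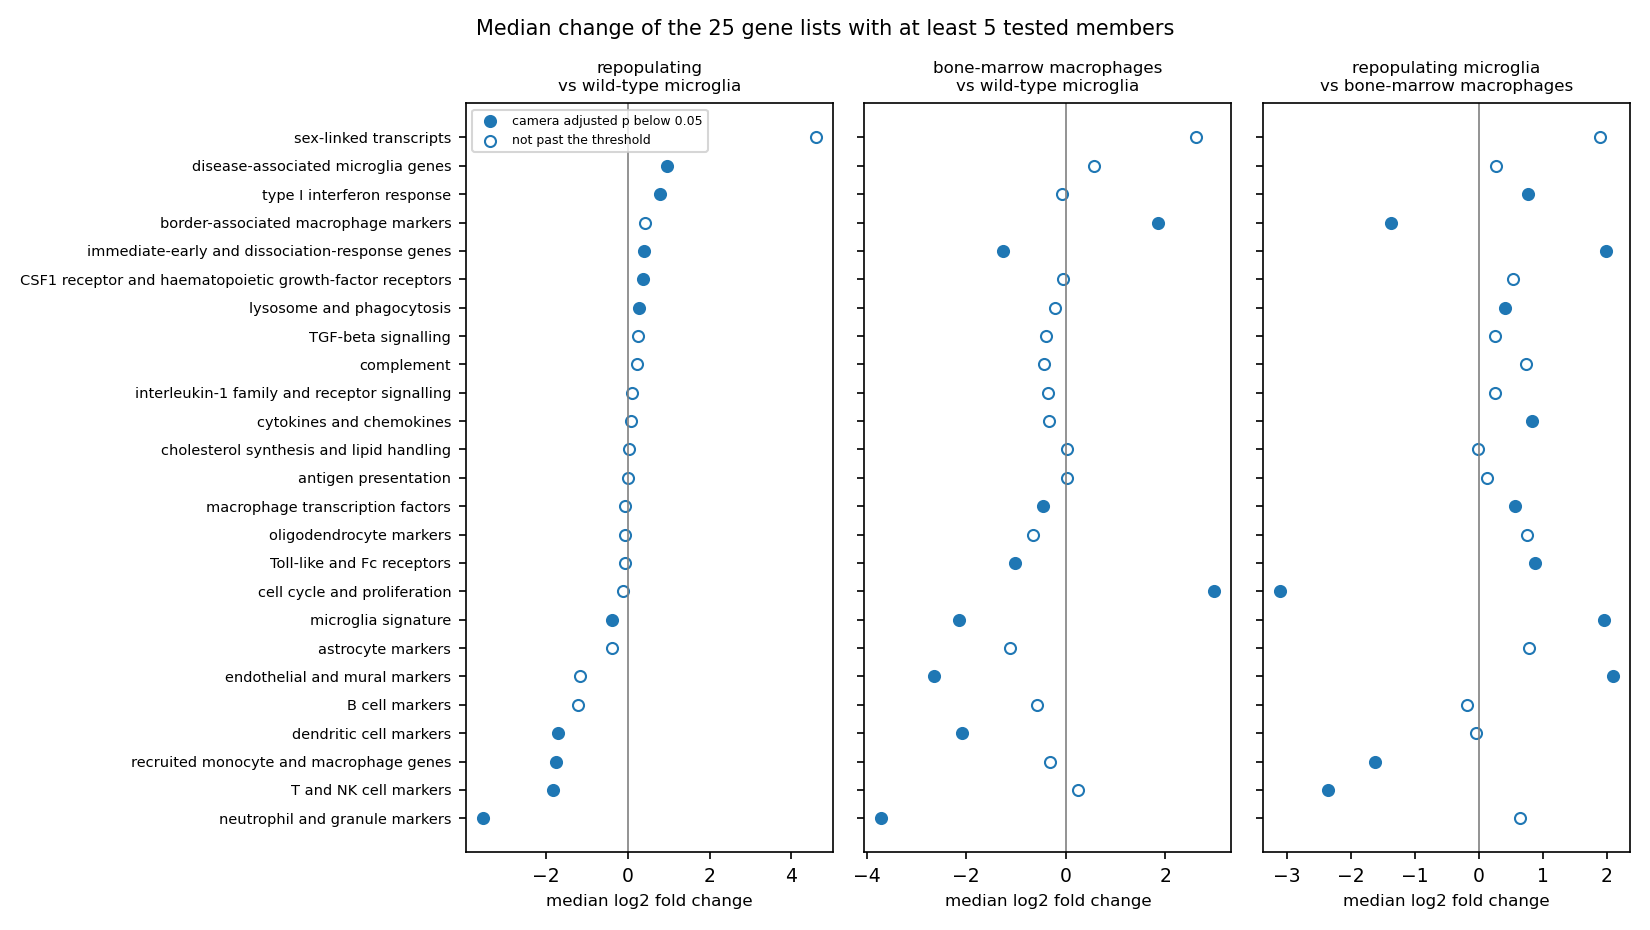
Median log2 fold change of the tested members of 25 gene lists in the 3 comparisons, with 1 row per list, filled points for a camera adjusted p under 0.05 and open points otherwise. Cell cycle genes stand at 2.99 in bone-marrow macrophages against wild-type microglia and at -0.11 in repopulating against wild-type microglia, and no filled point holds with an estimated correlation.

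The second comparison set bone-marrow macrophages against wild-type microglia, 2 macrophage populations of different labelled origin. Sall1 (chromosome 8, 89027235 to 89044162, minus strand) fell by 7.61 ± 0.57 on the log2 scale (SE), from 3618 ± 619 normalised counts (SD, n = 2) in wild-type microglia to 20.1 ± 13.9 (SD, n = 3) in bone-marrow macrophages. P2ry12 fell by 4.44 ± 0.20, from 71931 ± 4595 to 3341 ± 609. Col14a1, a fibril-associated collagen (chromosome 15, 55307750 to 55520803, plus strand), rose by 7.10 ± 0.55, from 10.5 ± 3.32 to 1545 ± 108. Top2a, a topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189, minus strand), rose by 3.94 ± 0.16, from 83.6 ± 13.3 to 1295 ± 117, and Apoe rose by 4.71 ± 0.30, from 2812 ± 846 to 73769 ± 18223. Their limma adjusted p-values were 3.17e-05, 5.36e-06, 3.62e-05, 2.91e-06 and 1.77e-05. No read of Eva1a, which encodes a lysosomal membrane protein, was counted in bone-marrow macrophages. They were at least 236-fold lower than wild-type microglia against a floor of 3 reads over the group. Of other microglial genes, Tmem119 and Siglech stood at 10304 ± 955 and 1711 ± 79.9 (SD) in bone-marrow macrophages. Wild-type microglia held 34945 ± 1549 and 6494 ± 107. These levels alone do not tell whether the bone-marrow macrophages were taken from marrow or from brain.

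Limma called 4960 genes, 2428 higher and 2532 lower in bone-marrow macrophages, 2963 of them at least 2-fold changed, while edgeR called 5040 and DESeq2 5222. With equal totals per library the median log2 fold of all genes moved from -0.01 to 0.13 and the 5069 calls split into 3000 higher and 2069 lower. Without wild-type replicates 1 and 2 the count was 2867 and 3041.

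The microglia signature and the cell cycle genes moved almost as blocks. In bone-marrow macrophages 39 of 41 signature genes fell, 40 adjusted over the list alone, with a median of -2.14 (camera adjusted p = 5.73e-21, and adjusted p = 0.322 with an estimated correlation). Slc2a5, a fructose transporter, fell by 5.99 ± 0.18 (SE) and Sparc, a matrix glycoprotein, fell by 4.93 ± 0.19 (limma adjusted p = 8.16e-07 and 2.43e-06). All 45 cell cycle and proliferation genes rose by limma, also adjusted over the list alone, with a median of 2.99 (camera adjusted p = 2.54e-21, and adjusted p = 0.352 with an estimated correlation). The mitotic kinesin Kif20a rose by 4.43 ± 0.29 (limma adjusted p = 1.93e-05). Mki67 (limma adjusted p = 0.0091) was not called without wild-type replicate 1 (0.0629), in a range of 8.71e-08 to 0.0629 over all settings. Border-associated macrophage markers rose in 10 of 17 cases and Colec12 fell, with equal counts adjusted over the list alone and a median of 1.85 (camera adjusted p = 0.00165, and adjusted p = 0.571 with an estimated correlation). The endocytic adaptor Dab2 rose by 3.89 ± 0.25, from 223 ± 58.5 (SD, n = 2) to 3267 ± 33.5 (SD, n = 3). The sialic-acid-binding lectin Siglec1 rose by 3.71 ± 0.33 (limma adjusted p = 1.91e-05 for Dab2 and 7.45e-05 for Siglec1).

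Immediate-early genes fell in 19 of 30 cases in bone-marrow macrophages and Hsp90aa1 rose, with 21 lower and 2 higher adjusted over the list alone and a median of -1.26 (camera adjusted p = 6.54e-06, and adjusted p = 0.571 with an estimated correlation). The small GTPase gene Gem fell by 5.16 ± 0.42 (SE) and its relative Rhob fell by 2.66 ± 0.23 (limma adjusted p = 4.88e-05 and 6.48e-05). Hsp90aa1 was not called without any 1 bone-marrow macrophage or wild-type replicate. Toll-like and Fc receptor genes fell in 15 of 22 cases and Tlr8 rose, with equal counts adjusted over the list alone and a median of -1.01 (camera adjusted p = 8.26e-05, and adjusted p = 0.571 with an estimated correlation). Tlr3, the double-stranded RNA receptor, fell by 2.08 ± 0.21 (limma adjusted p = 0.000114), and Tlr8 was not called without wild-type replicate 1 or 2. Macrophage transcription factors fell in 17 of 38 cases while Nfkb2, Zeb2, Runx2 and Runx3 rose, with 19 lower and 5 higher adjusted over the list alone and a median of -0.45 (camera adjusted p = 0.00434, and adjusted p = 0.571 with an estimated correlation). Klf2, a factor of quiescent leukocytes, fell by 3.72 ± 0.34 (limma adjusted p = 7.51e-05). Without wild-type replicate 1, 2 transcription factors were called higher and 11 lower, and without wild-type replicate 2, 9 lower.

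Neutrophil markers fell in 14 of 16 cases in bone-marrow macrophages, 15 adjusted over the list alone, with a median of -3.71 (camera adjusted p = 1.54e-08, and adjusted p = 0.352 with an estimated correlation). Ngp fell by 4.39 ± 0.21 (SE; limma adjusted p = 5.36e-06). Endothelial and mural markers fell in 11 of 14 cases, also adjusted over the list alone, with a median of -2.65 (camera adjusted p = 0.000587, and adjusted p = 0.571 with an estimated correlation). The junction protein Pecam1 fell by 4.81 ± 0.72 (limma adjusted p = 0.00103), and 4 of these markers were called lower without wild-type replicate 2. Dendritic cell markers fell in 7 of 13 cases, also adjusted over the list alone, with a median of -2.09 (camera adjusted p = 0.00165, and adjusted p = 0.322 with an estimated correlation). The actin bundler Fscn1 fell by 6.01 ± 0.43 (limma adjusted p = 2.53e-05).

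In the interleukin-1 family and receptor signalling list 12 of 33 genes fell in bone-marrow macrophages and Nlrc4, Irak1, Map3k7 and Irak4 rose, with 13 lower and 4 higher adjusted over the list alone and a median of -0.36 (camera adjusted p = 0.251). The inflammasome sensor Nlrc4 rose by 4.23 ± 0.37 (SE), from 5.19 ± 1.29 (SD, n = 2) to 114 ± 10.5 (SD, n = 3). Il1rl1, the interleukin-33 receptor, fell by 1.81 ± 0.25 (limma adjusted p = 6.96e-05 for Nlrc4 and 0.000613 for Il1rl1). Il1a fell by 1.16 ± 0.28 to 398 ± 112 (limma adjusted p = 0.00968). That call was lost without wild-type replicate 1 (0.0652) or 2 (0.0534), in a range of 0.00045 to 0.0652 over all settings. Il1r1 stood at 10.5 ± 3.65 (limma adjusted p = 0.552). The higher and lower counts of the list were 2 and 7 without bone-marrow macrophage replicate 1, and 1 and 3 or 2 and 4 without wild-type replicates 1 or 2. Without bone-marrow macrophage replicate 2, 2 were called higher.

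Of 27 disease-associated microglia genes 12 rose in bone-marrow macrophages and Ctsl, Csf1, Cd9, Cst7 and Hif1a fell, with 13 higher and 5 lower adjusted over the list alone. Axl rose by 3.67 ± 0.39 (SE; limma adjusted p = 0.000162). Their camera adjusted p was 0.0853, and 0.0391, 0.0375 and 0.0262 without bone-marrow macrophage replicate 1, wild-type replicate 1 and repopulating replicate 3, in a range of 0.0218 to 0.783 over the camera settings. Without wild-type replicate 1, 7 were called higher and 3 lower, and without wild-type replicate 2, 6 higher. The interferon and antigen presentation lists had medians of -0.08 and 0.03 but means of 0.12 and -0.14, with tests in the direction of the means that did not pass (camera adjusted p = 0.873 and 0.707).

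The third comparison set repopulating microglia against bone-marrow macrophages, which share the strain label. Sall1 rose by 7.39 ± 0.51 on the log2 scale (SE), from 20.1 ± 13.9 normalised counts (SD, n = 3) in bone-marrow macrophages to 3520 ± 2265 (SD, n = 3) in repopulating microglia, and P2ry12 rose by 3.29 ± 0.18. Adamts1, a secreted protease (chromosome 16, 85793827 to 85803113, minus strand), rose by 6.62 ± 0.24, from 2.16 ± 0.47 to 311 ± 51.3. Top2a fell by 4.00 ± 0.14 to 79.9 ± 3.71, and Apoe fell by 2.29 ± 0.27 to 15001 ± 3513. Limma adjusted p-values were 3.29e-05, 1.24e-05, 1.16e-06, 1.16e-06 and 0.000361. Cx3cr1, at 21834 ± 2385 and 20093 ± 1775, differed by log2 0.12 ± 0.15, less than the spread between replicates could tell from 0 (limma adjusted p = 0.597).

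Here limma called 3526 genes, 1826 higher and 1700 lower in repopulating microglia, 1919 of them at least 2-fold changed, while edgeR called 3568 and DESeq2 3819. With equal totals per library the median log2 fold moved from 0.00 to -0.25 and the 4096 calls split into 1172 higher and 2924 lower. The count was 2222 and 2333 without bone-marrow macrophage replicates 1 and 3 and 5348 without repopulating replicate 3.

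Il1a rose by 2.21 ± 0.25 (SE), from 398 ± 112 normalised counts (SD, n = 3) to 1832 ± 479.8 (SD, n = 3). Il1r1 rose by 1.59 ± 0.38, from 10.5 ± 3.65 to 32.7 ± 5.39 (limma adjusted p = 0.000283 for Il1a and 0.0135 for Il1r1). Nfkbia, a feedback inhibitor of NF-kappaB, rose by 1.70 ± 0.27 and Nlrc4 fell by 3.77 ± 0.33 (limma adjusted p = 0.00179 and 8.87e-05). Of 33 genes of the interleukin-1 family and receptor signalling 11 rose while Nlrc4 and Irak3 fell, with 12 higher and 3 lower adjusted over the list alone and a median of 0.26. The list did not pass (camera adjusted p = 0.0694), but passed without bone-marrow macrophage replicate 2 (0.0433) or repopulating replicate 3 (0.0228), in a range of 0.0228 to 0.434 over the camera settings. By fry its adjusted p was 0.0378 for 1 direction and 2.24e-06 for either. The higher count was 6 and 7 without bone-marrow macrophage replicates 1 and 2, with 1 lower each time, and 7 without bone-marrow macrophage replicate 3 or repopulating replicate 1. Leaving out repopulating replicate 3 gave 4 lower. Of the 30 immediate-early and dissociation-response genes, which cell isolation can induce, 22 were also higher in this comparison and 1 lower. Whether isolation had a part in the interleukin-1 differences was not tested.

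Microglia signature genes rose in 38 of 41 cases, also adjusted over the list alone, with a median of 1.95 (camera adjusted p = 2.51e-23, and adjusted p = 0.365 with an estimated correlation). Sparc rose by 5.24 ± 0.17 (SE) and Slc2a5 by 4.80 ± 0.16 (limma adjusted p = 7.56e-07 for Sparc and for Slc2a5). All 45 cell cycle and proliferation genes fell by limma, also adjusted over the list alone, with a median of -3.12 (camera adjusted p = 1.5e-29, and adjusted p = 0.365 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, fell by 3.55 ± 0.21 (limma adjusted p = 1.6e-05). Mki67 (limma adjusted p = 0.0269) was not called without any 1 bone-marrow macrophage replicate or without repopulating replicate 1 or 2, in a range of 3.58e-07 to 0.18 over all settings. Immediate-early genes rose in 22 of 30 cases and Hsp90aa1 fell, with 24 higher and 1 lower adjusted over the list alone and a median of 2.00 (camera adjusted p = 1.01e-10, and adjusted p = 0.365 with an estimated correlation). Lysosome genes rose in 16 of 33 cases and Gusb fell, with 19 higher and 2 lower adjusted over the list alone and a median of 0.40 (camera adjusted p = 2.01e-05, and adjusted p = 0.365 with an estimated correlation). Itgb3, an integrin subunit that binds matrix and apoptotic cells, rose by 4.18 ± 0.23 (limma adjusted p = 1.24e-05). Neither Hsp90aa1 nor Gusb was called without any 1 bone-marrow macrophage replicate. Hsp90aa1 was also not called without wild-type replicate 1 or 2 or repopulating replicate 2, and Gusb not without repopulating replicate 1, and 2 lysosome genes were called lower without repopulating replicate 2 or 3.

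Interferon response genes rose in 18 of 42 cases and Ifi203 fell, with 23 higher and 1 lower adjusted over the list alone and a median of 0.77 (camera adjusted p = 2.52e-05, and adjusted p = 0.434 with an estimated correlation). Ifit3, an interferon-induced protein, rose by 1.97 ± 0.29 (SE; limma adjusted p = 0.00112). Genes of the type I interferon response called higher numbered 11 without bone-marrow macrophage replicate 1 and 29 without repopulating replicate 3, and 2 were lower without repopulating replicate 1 or 3. Ifi203 was not called without any 1 bone-marrow macrophage replicate. Toll-like and Fc receptor genes rose in 13 of 22 cases while Tlr8 and Clec4d fell, with 14 higher and 2 lower adjusted over the list alone and a median of 0.88 (camera adjusted p = 4.56e-05, and adjusted p = 0.394 with an estimated correlation). Without bone-marrow macrophage replicate 2, 1 of these receptors was called lower. Macrophage transcription factors rose in 16 of 38 cases while Runx3, Pparg, Runx2 and Tfec fell, with 17 higher and 6 lower adjusted over the list alone and a median of 0.56 (camera adjusted p = 0.00104, and adjusted p = 0.394 with an estimated correlation). Egr2, an early growth response factor, rose by 3.63 ± 0.26 (limma adjusted p = 3.44e-05). Cytokines and chemokines rose in 16 of 33 cases while Cxcl1, Cxcl14, Igf1, Cxcl16 and Tnfsf13b fell, with 16 higher and 7 lower adjusted over the list alone and a median of 0.83 (camera adjusted p = 0.00894, and adjusted p = 0.434 with an estimated correlation). Cytokines called lower numbered 3, 2 and 3 without bone-marrow macrophage replicates 1, 2 and 3. Il6 rose by 3.91 ± 0.44 from 2.85 ± 2.17 (SD, n = 3) to 53.0 ± 16.0 (SD, n = 3; limma adjusted p = 0.000286). Endothelial and mural markers rose in 9 of 14 cases, 10 adjusted over the list alone, with a median of 2.1 (camera adjusted p = 0.00103, and adjusted p = 0.394 with an estimated correlation). The vascular growth-factor receptor Kdr rose by 3.03 ± 0.41 (limma adjusted p = 0.000748). Only 4 and 3 endothelial and mural markers were called higher without bone-marrow macrophage replicates 2 and 3.

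Genes of recruited monocytes and macrophages fell in 22 of 40 cases while Ifitm3 and Ly6c1 rose, with 25 lower and 3 higher adjusted over the list alone and a median of -1.63 (camera adjusted p = 1.26e-06, and adjusted p = 0.394 with an estimated correlation). Ccr2, the receptor that draws monocytes out of marrow, fell by 2.39 ± 0.44 (SE; limma adjusted p = 0.00365). Without bone-marrow macrophage replicate 1 or 2, 14 recruited monocyte and macrophage genes were called lower. The higher count was 1 without bone-marrow macrophage replicate 1 or repopulating replicate 1 or 2, and neither Ifitm3 nor Ly6c1 was called without bone-marrow macrophage replicate 2 or 3. Border-associated macrophage markers fell in 11 of 17 cases and Colec12 rose, with 12 lower and 1 higher adjusted over the list alone and a median of -1.38 (camera adjusted p = 0.00103, and adjusted p = 0.394 with an estimated correlation). The mannose receptor Mrc1 fell by 3.43 ± 0.40 (limma adjusted p = 0.000356). Without bone-marrow macrophage replicate 1 or 2, 7 border-associated macrophage markers were called lower, and without repopulating replicate 2, 2 were called higher. T and NK cell markers fell in 8 of 13 cases, also adjusted over the list alone, with a median of -2.36 (camera adjusted p = 0.00257, and adjusted p = 0.394 with an estimated correlation). The surface glycoprotein Thy1 fell by 3.36 ± 0.67 (limma adjusted p = 0.00564). T and NK cell markers called lower numbered 3, 4 and 5 without bone-marrow macrophage replicates 1, 2 and 3 and 5 without repopulating replicate 1. Antigen presentation, dendritic cell and cholesterol genes had medians of 0.13, -0.04 and -0.02 but means of -0.004, 0.31 and 0.04, with tests in the higher direction that did not pass (camera adjusted p = 0.453, 0.751 and 0.861).

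Changes in repopulating microglia and in bone-marrow macrophages, each against the same 2 wild-type libraries, correlated at r = 0.572 across the 11415 genes, which are not independent replicates. Unchanged groups simulated against shared wild-type libraries gave a mean r of 0.601 and a highest of 0.638 in 100 simulations. The simulated r follows from the group sizes whatever the spread, so it does not tell how much of the observed r comes from the shared controls. The covariance was 0.601 against a simulated 0.078, a difference of 0.523, and 74.5% of genes had the same sign against a simulated 70.5%. Among calls, 441 genes were higher in both comparisons, where independent lists would share 118, and 322 were lower in both against 94.9. Without wild-type replicate 1 the shared genes numbered 33 higher and 22 lower, against 4.7 and 3.7 for independent lists, and without wild-type replicate 2 they numbered 67 and 58, against 9.9 and 9.7. They numbered 213, 223 and 221 higher and 145, 164 and 163 lower without bone-marrow macrophages 1, 2 and 3, 203 and 161 without repopulating replicate 1, and 1319 and 959 without repopulating replicate 3. Opposite calls numbered 20 and 13 against 123 and 91. The 2 wild-type libraries are too few to split, so part of the excess may come from the shared controls.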

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

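The fits with a Y-linked covariate and with length and GC trends removed were chosen after the result was seen; the others were planned. Of 9215 values of named genes under the alternatives, 8601 kept their side of the threshold, 41 of them with another sign while uncalled in both, 562 lost the call, 51 gained it, and 1 gained it with another sign: Xist, uncalled at log2 -0.06 in repopulating microglia against bone-marrow macrophages, stood at 1.78 with the Y-linked covariate. Gene lists kept their side of the threshold in 1940 of 2088 values. For repopulating against wild-type microglia the count of 983 became 78 with only the libraries of these groups (all 78 at least 2-fold), where 3 residual degrees of freedom remain, 2807 with library weights (1145 at least 2-fold), 1625 with DESeq2, 325 with the Y-linked covariate (277 at least 2-fold) and 1518 with trends removed, and beyond the smaller fit the cause was not tested. With library weights 6409 genes were called in repopulating microglia against bone-marrow macrophages. Lists past the threshold fell to 0 in all 3 comparisons with an estimated correlation and rose to 21, 24 and 22 by fry's test of change in either direction, for repopulating and bone-marrow macrophages against wild type and for repopulating against bone-marrow macrophages. By fry's directional test they numbered 7, 11 and 18 against 10, 9 and 12 with camera, and the microglia signature (adjusted p = 0.0833), type I interferon response (0.0687), T and NK cell markers (0.0592) and immediate-early and dissociation-response genes (0.258) no longer passed for repopulating against wild-type microglia.

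Leaving out 1 library at a time gave 67 to 2958 genes (67 to 1188 at least 2-fold) for repopulating against wild-type microglia, 2867 to 7030 for bone-marrow macrophages against wild-type microglia and 2222 to 5348 for repopulating microglia against bone-marrow macrophages. With 1 wild-type library left, that library is assumed to vary as the other groups do. Of 94 named calls in the first comparison, 71 and 59 were lost without wild-type replicates 1 and 2 and 0 without repopulating replicate 3.

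With the replicate number as a replicate block, 733, 4811 and 3564 genes were called. Deviations of same-numbered libraries correlated at -0.085, -0.001 and 0.133 between bone-marrow macrophages and repopulating microglia. Differently numbered libraries of these groups correlated at -0.139 to 0.149. Same-numbered deviations correlated at 0.037 and -0.053 between bone-marrow macrophages and wild type, and at 0.244 and -0.24 between wild type and repopulating microglia. The deviations of the wild-type libraries mirror each other, so the values with wild type are not independent. These correlations showed no clear pairing by number but cannot exclude it. At these depths 1 read was worth 0.57 to 1.48 normalised counts, which limits genes near the filter of 10.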

Other observations

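The tests of depth, of the joint trend with length and GC content, and of both other patterns below, and the count of differences among shared genes, were chosen after the result was seen; the tests of single trends with length and with GC content and of other splits were written before. Of the 441 genes higher than wild type in both DTRmg-labelled groups, limma called 129 lower and 10 higher in repopulating microglia than in bone-marrow macrophages and did not call 302. Of the 322 genes lower in both it called 125 higher and 20 lower and did not call 177. Cx3cr1 stood at log2 -1.61 in repopulating microglia and -1.72 in bone-marrow macrophages (limma adjusted p = 0.00179 and 0.00011), and these groups were at 0.12 from each other (0.597). Igfbp4 (1.78 and 1.85), Slfn5 (2.28 and 2.09) and Eif2ak2 (1.82 and 2.08) were higher in both, and Cd209a (-2.92 and -2.79), Chi3l3 (-3.78 and -3.83) and Cd24a (-2.98 and -3.05) lower in both, and these 7 genes were picked for near-equal folds after their values were seen.

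Genes higher in both groups than in wild-type microglia numbered 441, or 33 and 67 without wild-type replicates 1 and 2. RNA of cells like the bone-marrow macrophages in the repopulating libraries would carry all their abundant transcripts at about 1 share, but the 45 cell cycle genes stood at a median of -0.004 of the bone-marrow level above wild type (quartiles -0.047 and 0.026), and 24 genes rare in wild type and abundant in bone-marrow macrophages at 0.064 (quartiles 0.033 and 0.179), against 0.784 for the 441 genes. The 441 genes were chosen for being high in the repopulating libraries, which raises their share, while the other 2 sets were not. Their low shares argue against such RNA as the whole cause, but not against a small share of it. In repopulating against wild-type microglia the median log2 fold of the 441 genes was 1.08 (quartiles 0.85 and 1.4). The median of all genes moved by at most 0.13 between scalings. Because the 441 genes were chosen by their calls, their folds had to be large, so this comparison cannot decide on scaling. The shared wild-type libraries, the shared strain label and library composition (ribosomal protein genes took 8.45% to 8.83% of bone-marrow macrophage, 6.04% to 9.26% of repopulating and 4.26% to 4.90% of wild-type reads) stay open, and an effect of strain may be a biological candidate that was not tested.

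Neutrophil markers were higher in both wild-type libraries than in the 3 repopulating ones for 15 of 16 genes, S100a8 at 9011 and 7656 normalised counts against 911, 731 and 343, the exception being Mmp9 at 680 and 865 against 1892, 3138 and 66.8. The labels name a sort but no gate, and RNA of neutrophils may be a source: 11 of the 16 folds lay within 2-fold of their median of -3.56 (SD 1.33), but in 2 wild-type libraries it cannot be told apart from a change within the cells. Elane, Mpo, Prtn3 and Fcnb stood at 168.8, 303.5, 131.4 and 69.5 in wild-type replicate 1, against 36.6, 73.2, 30.5 and 25.4 in replicate 2. Other markers did not differ so, with Ngp at 4770 and 4885 and Camp at 1800 and 1561. These genes were picked after their values were seen. If the wild-type libraries held fewer microglia and more of every other cell type alike, markers of all these types would fall by about 1 factor. Markers of neurons, astrocytes, oligodendrocytes and endothelial cells had a median log2 fold of -0.71 (quartiles -1.25 and -0.05). The neutrophil markers had quartiles of -4.17 and -3.17. Wild-type medians of the neuron, astrocyte, oligodendrocyte and endothelial lists were 15.1, 21.8, 104.6 and 31.6 normalised counts, and folds of genes with low counts are understated. With border-associated macrophage markers at 0.42 and the microglia signature at -0.38, this argues against such an even rise as the whole cause. It does not argue against a lower share of microglia with an uneven rise of other cell types. Markers of other blood cells lay between, at -1.83 (quartiles -3.38 and -0.38) for T and NK cells, -1.72 (-2.94 and -0.24) for dendritic cells, -1.76 (-3.32 and -0.28) for recruited monocytes and macrophages and -1.23 (-1.69 and 0.36) for B cells, so a larger share of several blood cells stays open, as do repopulation and strain, which were not tested.

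Replicate 3 of the repopulating microglia stood apart from replicates 1 and 2. It was not the shallowest library, with 6944167 reads against 9523997 and 5918944 in replicates 1 and 2, so lower depth could not set it apart from both. Thinning the libraries to equal reads was therefore no strong test. Replicates 1 and 2 still correlated better with each other than with replicate 3, by 0.042 (0.978 against 0.936 and 0.92). A trend with transcript length took 0.144 of the variance of replicate 3 less the mean of the others over 7353 genes, from log2 -0.6 at a median length of 862 bases to 0.57 at 9701, and a trend with GC content 0.125, so neither alone is the whole cause. Both together took 0.372, and removing them moved the correlations to 0.952 and 0.937 against 0.979, so a joint technical trend may be part of the difference and stays open, as does the mixture of Xist and Y-linked transcripts in this library. Ctsk, Acp5 and Atp6v0d2 stood at 70.3, 163.6 and 15.0 normalised counts in replicate 3. Replicate 1 held 1928, 2570 and 250.3 of them, and replicate 2 held 4203, 4186 and 515.1. Sall1 and Nes went the other way, at 6101 and 278.7 in replicate 3. They stood at 2594 and 60.45 in replicate 1 and at 1864 and 67.89 in replicate 2. These genes were picked after their values were seen. No biological explanation was tested, since the design gives none within a group.

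Repopulating microglia against bone-marrow macrophages gave 3526 genes, and among the 10 splits of the 6 libraries into 3 and 3 only the real one, 1 of 10, gave as many, the highest other giving 3. These splits are too few for a share under 0.05. Every other split also mixed both groups on each side, which widens the spread within a side. Few calls were therefore likely from the start, and the splits cannot decide whether the calls arose by chance.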
